A study of Mus musculus with 10 samples.

How the data were processed

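Total RNA from minced whole sections of mouse terminal ileum was labelled with a 3′ in vitro transcription protocol and hybridised to Affymetrix arrays of the type Mouse Genome 430A 2.0, per the labels' protocols. The authors deposited 1 table of log2 values for all 10 arrays, made with RMA in Affymetrix Expression Console, per the submitters' processing notes, whose versions are not given in the sources used here. RMA corrects background, normalises by quantiles and summarises probes. The sources do not say whether all arrays were normalised together, and array medians lay between 7.09 and 7.25. Levels of different probe sets were not set against each other. The series text states that interference from bacterial RNA was reduced through the choice of probe sets near the poly-A tail.

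The table held 22690 probe sets, of which 64 were controls. Gene names came from the platform's annotation, updated through entrez IDs against a RefSeq table of assembly GRCm38.p6, in which 20351 probe sets matched and 0 symbols changed. A single symbol was listed for 20380 probe sets, several for 691 and none for 1555, and a probe set with several symbols or none named no gene. Each of 12393 genes was represented by its probe set with the highest mean over all arrays, a choice that mattered for the 4956 genes with more than 1. Olfm4 and Muc2, fixed for naming, had no single-symbol probe set and are not reported here. No coordinates are given, since the sources name no genome build.

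Groups were taken from the labels. Before the data were examined, the comparisons, tests, gene lists, rule for named genes and most alternatives were fixed. limma 3.58.1 in R 4.3.3 fitted group means over all 10 arrays, with empirical Bayes moderation and no covariate, so that the 3 groups shared 1 estimate of the spread, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Of 47 lists of genes written from textbook knowledge, 45 with at least 5 measured genes were tested with camera at a preset correlation of 0.01. Some lists share genes, so their results are not independent. Members were also counted after adjustment over their list alone, in each list and comparison by itself. That count was not the fixed test of genes and is not corrected for the number of lists. The 4 measured erythroid genes were too few to test, and sex-linked genes served only to describe the arrays. Named genes were, in each comparison, the 10 largest rises and 10 largest falls among genes that passed with groups that did not overlap, up to 4 members of each list with the largest absolute difference, and 12 fixed genes.

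Replicate numbers are shared between the groups. A wildtype and a Min array with the same number cannot come from the same animal, since their genotypes differ. For the Min groups the labels do not tell whether the same number means the same animal, so the numbers were not treated as pairs. No array was a copy of another: the closest pair, polyp-bearing replicates 2 and 3, had exactly equal values, as deposited, for 10 of 12393 genes and differed with an SD of 0.294.

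The procedure was tested on simulated data of 12393 genes with 100 genes changed by 1 and 100 by 2 on the log2 scale. For polyp-bearing against polyp-free sections, 84% and 98% were recovered, for polyp-free against wildtype 67% and 95%, and for polyp-bearing against wildtype 73% and 94%. All 5 lists shifted by 1 on the log2 scale in every member were called in each comparison. Smaller shifts, as in most lists reported below, were not simulated. There were 1, 0 and 0 false list calls of 37, and 15, 6 and 16 genes were called falsely. The simulated genes varied independently of each other. The false list calls therefore do not tell how often camera calls a list whose genes vary together, as in tissue.

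Alternatives were the replicate number as a block, cyclic loess, median centring, a filter on the lowest 40% of genes, other uses of probe sets, a trended robust prior, array weights, fits on the compared groups only, a fold of at least 2, an estimated correlation, fry and leaving out each array. Chosen after seeing the data were leaving out polyp-free replicate 1 and polyp-bearing replicate 4 together, and covariates for the 3′ to 5′ control ratio and for the level of proximal small intestine genes.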

Results

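Expression was measured in whole sections of terminal ileum from 12-week-old B6 mice on 10 Affymetrix Mouse Genome 430A 2.0 arrays. Min mice carry 1 mutant allele of Apc, the gene for a brake on Wnt signalling, and develop intestinal adenomas. Sections had been sorted by eye into those with and without polyps, which gave 3 groups: wildtype sections without polyps (n = 2), Min sections without polyps (n = 4) and Min sections with polyps (n = 4). The labels call the arrays biological replicates and do not say which sections came from the same animal. Values are log2 RMA expression, and 12393 genes were tested with 1 probe set each. The small number of arrays, above all the 2 wildtype arrays, limits the precision of every difference.

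The arrays differed in ways other than their group. The log2 difference between the 3′ and 5′ control probe sets of Actb, a sign of RNA integrity and labelling, averaged 1.19 ± 0.10 (SD, n = 2) in wildtype, 1.73 ± 0.75 (SD, n = 4) in polyp-free Min and 2.27 ± 0.38 (SD, n = 4) in polyp-bearing Min sections. An exact two-sided permutation test of polyp-bearing against wildtype arrays gave p = 0.0667, the smallest p that 4 against 2 arrays allow, and 0.267 after Benjamini-Hochberg adjustment over 12 tests. Polyp-free replicate 1 and polyp-bearing replicate 4 had the highest values, 2.77 and 2.83, and the highest hybridisation controls, 12.59 and 12.36, against 11.25 to 11.74 elsewhere. They hold 1 array of each Min group, too few for a comparison of their own. Without both, the counts of changed genes were 0 between the Min groups in limma, 22 between polyp-free and wildtype and 1596 between polyp-bearing and wildtype sections. Xist was low and the Y-linked genes Eif2s3y and Kdm5d were high in replicate 3 of both Min groups (Xist 6.23 and 5.93), while the other 8 arrays had Xist between 12.53 and 13.03. By these genes the replicate 3 arrays of the Min groups were male and the other 8, with both wildtype arrays, female. Sex was therefore not balanced between Min and wildtype arrays, and the fits held no term for it.

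Apc itself was at 9.41 ± 0.06 (SD, n = 2) in wildtype, 9.25 ± 0.26 (SD, n = 4) in polyp-free and 9.42 ± 0.16 (SD, n = 4) in polyp-bearing sections, and passed the test in no comparison. The Min allele is a point mutation, so the level of the transcript does not check the labels.

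Polyp-bearing Min sections were set against wildtype sections to see how ileum with adenomas differs from ileum without the mutation. Genes of Wnt signalling, matrix breakdown, mast cells and fetal-type epithelium were higher in the polyp-bearing sections, and genes of absorptive and enteroendocrine cells, fatty acid oxidation and MHC class II were lower. As groups these passed with camera, but none did with an estimated correlation (adjusted p = 0.14 to 0.501 with an estimated correlation). The largest measured rise was that of Wfdc18 (Entrez gene 14038), a secreted whey acidic protein family member, from 5.80 ± 0.34 (SD, n = 2) to 13.42 ± 0.58 (SD, n = 4), a log2 difference of 7.62 ± 0.56 (SE), with all 4 arrays above both wildtype arrays (limma, Benjamini-Hochberg adjusted p = 0.000389). Wif1 (Entrez gene 24117), a secreted Wnt inhibitor, rose by 6.26 ± 0.77 (SE) from 3.86 ± 0.42 (SD, n = 2) to 10.12 ± 0.66 (SD, n = 4), with a limma adjusted p of 0.00235. In the wildtype arrays, which had high Xist, Y-linked genes read from 3.16 (Eif2s3y) to 4.56 (Uty). The wildtype mean of Wif1 lay in this range, near background. Its rise may thus be understated, and the order of the largest rises is uncertain. Ccl20 (Entrez gene 20297), a chemokine made by epithelium, fell by 2.15 on the log2 scale, from 10.04 ± 0.35 (SD, n = 2) to 7.89 ± 0.58 (SD, n = 4), with a limma adjusted p of 0.0051.

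Among the other largest rises were the amino acid transporter Slc38a4, from 3.67 ± 0.11 (SD, n = 2), in the range of the Y-linked genes, to 10.67 ± 0.74 (SD, n = 4). They also held the protease Ctse (5.42), the transcription factor Sox17 (5.31), the goblet cell protein Retnlb (5.09), the iron-siderophore binding protein Lcn2 (4.85) and the plasminogen activator Plat (4.80). Only 1 of the 2 probe sets of Ctse went up. The largest falls after Clca3b (-2.19) and Ccl20 were those of Angptl4 (-1.98), an inhibitor of lipoprotein lipase, Gsdme (-1.87), Serpina1b (-1.84), the retinaldehyde dehydrogenase Aldh1a1 (-1.81), Dab1 (-1.77), the gluconeogenic enzyme Fbp1 (-1.73), the retinol esterifying enzyme Lrat (-1.68) and the vitamin transporter Slc5a6 (-1.68). For Angptl4, 1 of the 2 probe sets went the other way. The call of Clca3b was kept in 15 of 22 other settings, where its difference ranged from -2.41 to -1.04.

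Wnt target genes rose as a group in polyp-bearing against wildtype sections, with a median log2 difference of 1.28 over 26 measured genes (camera adjusted p = 1.66e-12; adjusted p = 0.291 with an estimated correlation). Of these, 18 rose and none fell over all genes tested, and 19 rose and 1 fell when adjusted over the list alone. Notum, a secreted enzyme that inactivates Wnt proteins, differed by 3.73, Dkk2 by 3.82 and Tnfrsf19 by 2.89. The difference of Tnfrsf19 ranged from 1.37 to 3.84 over 22 other settings. Dkk2 was at 4.16 and 3.81 in wildtype, in the range of the Y-linked genes there. Axin2, a classic target, differed by 0.23 ± 0.22 (SE) and did not pass (limma adjusted p = 0.614), and its 2 probe sets went in opposite directions. Intestinal stem cell genes also rose (median 0.42 over 12 genes, camera adjusted p = 0.000312; adjusted p = 0.347 with an estimated correlation). There were 4 rises over all genes and 5 adjusted over the list alone. They included Prom1 (1.68), the ubiquitin ligase Rnf43 (1.45), the receptor Lgr5 (1.33, limma adjusted p = 0.0192) and Sox9 (1.22). Rnf43, Lgr5 and Sox9 are also on the Wnt list, so the results of these lists are not independent. Myc differed by 0.66 ± 0.19 (SE) and missed the threshold (limma adjusted p = 0.0531).

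Growth genes rose with them. Ribosome biogenesis genes had a median of 0.64 over 19 genes (camera adjusted p = 1.66e-08; adjusted p = 0.347 with an estimated correlation), with 9 rises over all genes and 10 adjusted over the list alone, Wdr43 (1.01) and Nop56 (0.99) among them. Cell cycle genes had a median of 0.51 over 26 genes (camera adjusted p = 1.19e-05; adjusted p = 0.501 with an estimated correlation). There were 5 rises over all genes and 6 adjusted over the list alone, such as the ribonucleotide reductase subunit Rrm2 (1.31) and the replication helicase subunit Mcm4 (1.17). Glycolysis genes had a median of 0.74 over 11 genes (camera adjusted p = 0.000312; adjusted p = 0.347 with an estimated correlation), with 4 rises over all genes and, adjusted over the list alone, 7 rises and 1 fall. The glucose transporter Slc2a1 rose by 2.21 and Pgk1 by 0.82.

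Matrix remodelling protease genes rose (median 0.72 over 16 genes, camera adjusted p = 1.15e-06; adjusted p = 0.347 with an estimated correlation). There were 8 rises both over all genes and adjusted over the list alone. The collagenase Mmp13 rose by 3.60, and Timp1, an inhibitor of such proteases, by 2.49, and the membrane-bound protease Mmp14 went from 8.08 ± 0.29 (SD, n = 2) to 10.58 ± 0.50 (SD, n = 4). YAP and fetal-type epithelial genes had a median of 1.16 over 12 genes (camera adjusted p = 0.000152; adjusted p = 0.347 with an estimated correlation), with 6 rises and 1 fall both over all genes and adjusted over the list alone. Anxa1 (4.42), the chaperone Clu (4.34) and the alarmin Il33 (3.33) led them. Ptgs2, the inducible enzyme of prostaglandin synthesis, rose by 1.98 ± 0.55 (SE; limma adjusted p = 0.0452), a call kept in 8 of 21 other settings, where the adjusted p ranged from 0.00739 to 0.321.

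Mast cell genes rose (median 0.92 over 12 genes, camera adjusted p = 4.45e-05; adjusted p = 0.347 with an estimated correlation). There were 5 rises over all genes and 7 adjusted over the list alone. The mucosal mast cell proteases Mcpt2 (5.08) and Mcpt1 (4.83), which belong to a family whose members can share probes, stood beside Cpa3 (3.26) and the IgE receptor chain Fcer1a (2.95). Plasma cell genes rose (median 0.45 over 11 genes, camera adjusted p = 0.0065; adjusted p = 0.347 with an estimated correlation), with 3 rises over all genes and 5 adjusted over the list alone, Igha (1.26) and Jchain (1.24) among them, where immunoglobulin genes can share probes. B cell genes passed too (median 0.88 over 13 genes, camera adjusted p = 0.0421; adjusted p = 0.646 with an estimated correlation). There was 1 rise both over all genes and adjusted over the list alone, and their level varied between arrays of 1 group, from 5.81 to 7.90 in polyp-free sections. MHC class II genes fell (median -0.65 over 6 genes, camera adjusted p = 0.000167; adjusted p = 0.347 with an estimated correlation), with 3 falls over all genes and 6 adjusted over the list alone, Cd74 (-1.05), H2-Eb1 (-0.77) and H2-DMa (-0.68) among them. The fixed immune genes Il10 (-0.09), Il17a (0.02), Foxp3 (-0.15) and Reg3g (0.07) and the Paneth cell gene Lyz1 (-0.16) did not pass.

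Absorptive enterocyte genes fell (median -0.95 over 20 genes, camera adjusted p = 7.56e-06; adjusted p = 0.501 with an estimated correlation), with 2 falls over all genes and 8 adjusted over the list alone, the brush border protease Mep1a (-1.62) among them. Xenobiotic metabolism genes fell (mean -1.08 over 18 genes, camera adjusted p = 3.32e-05; adjusted p = 0.443 with an estimated correlation), with 5 falls over all genes and 6 adjusted over the list alone. Beside both groups, genes of the proximal small intestine varied widely within every group: their mean level was 7.74 and 9.12 in the 2 wildtype arrays, 7.54 to 9.26 in polyp-free and 7.62 to 8.66 in polyp-bearing arrays. Lct and Fabp1 are on both the proximal and the absorptive enterocyte list. Fatty acid oxidation genes fell (median -0.64 over 13 genes, camera adjusted p = 9.42e-05; adjusted p = 0.291 with an estimated correlation). There were 5 falls over all genes and 7 adjusted over the list alone, such as the peroxisomal enzyme Ehhadh (-1.48) and the mitochondrial enzyme Hadha (-1.03). Enteroendocrine cell genes fell (median -0.62 over 22 genes, camera adjusted p = 7.56e-06; adjusted p = 0.14 with an estimated correlation), with 7 falls over all genes and 9 adjusted over the list alone, the hormones Nts (-1.57), Sst (-1.14) and Sct (-1.12) among them. Ileal bile acid genes fell (median -0.76 over 6 genes, camera adjusted p = 0.0284; adjusted p = 0.347 with an estimated correlation), where the bile acid exporter subunit Slc51a (-0.93) was the 1 fall both over all genes and adjusted over the list alone. Smooth muscle genes fell (median -0.70 over 12 genes, camera adjusted p = 0.00207; adjusted p = 0.501 with an estimated correlation). There was 1 fall both over all genes and adjusted over the list alone.

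In all, 1314 of 12393 genes changed between polyp-bearing and wildtype sections at a limma Benjamini-Hochberg adjusted p under 0.05, 799 of them higher and 515 lower, and 485 differed by at least 2-fold. With each array centred on its median only, the split was 630 higher and 805 lower. Of 45 gene lists, 10 rose and 9 fell with camera, and none passed with an estimated correlation. When single arrays were left out, the mean difference of 5 lists moved by over 1.5 times, as without wildtype replicate 2 for absorptive enterocyte (-1.09 to -0.54), xenobiotic metabolism (-1.08 to -0.68), B cell (0.75 to 0.45) and stem cell genes (0.66 to 0.44). The gene count was 363 without wildtype replicate 1 and 126 without wildtype replicate 2, where the lone wildtype array is assumed to vary like the others, 746 without polyp-bearing replicate 2, 725 without polyp-bearing replicate 4 and 2205 without polyp-free replicate 1. Array weights gave 2859 genes, the 3′ to 5′ ratio as a covariate 2155 and the replicate number as a block 522. That block joins wildtype and Min arrays, which cannot be the same animal, so it is no check of pairing here.

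**Figure D1:**
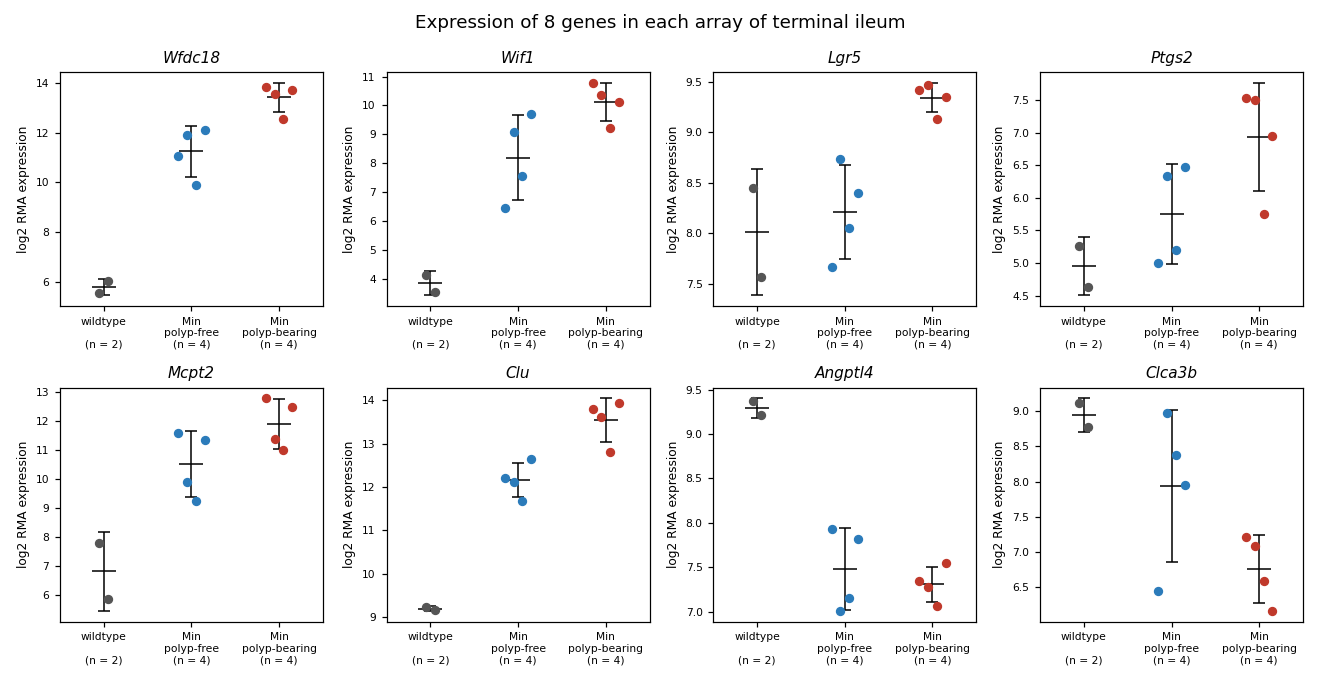
Log2 RMA expression (vertical axis) of 8 genes in each of the 10 arrays, by group (horizontal axis); points are arrays, and bars give the mean and SD. Wfdc18 lay at 5.80 in wildtype, 11.25 in polyp-free and 13.42 in polyp-bearing sections on average, and Angptl4 at 9.29, 7.48 and 7.31.

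Polyp-free Min sections were set against wildtype sections to see what differs in ileum of mutant mice where no polyp was seen. Wfdc18 rose by 5.44 ± 0.56 (SE; limma adjusted p = 0.013), from 5.80 ± 0.34 (SD, n = 2) to 11.25 ± 1.01 (SD, n = 4), and Clu (Entrez gene 12759) by 2.97 ± 0.31 (SE; limma adjusted p = 0.013), from 9.20 ± 0.05 (SD, n = 2) to 12.16 ± 0.40 (SD, n = 4). Ifitm1 (3.27), Anxa1 (3.26), the coagulation factor subunit F13a1 (2.12), Pmepa1 (1.59) and the myosin light chain Myl7 (1.27) rose as well. Unseen adenoma tissue in these sections was not excluded as a source of these rises. Angptl4 (Entrez gene 57875) was the 1 gene that fell, by 1.81 on the log2 scale (limma adjusted p = 0.0483), from 9.29 ± 0.11 (SD, n = 2) to 7.48 ± 0.46 (SD, n = 4), and its difference was -0.91 with the mean of its 2 probe sets. Of 22 other settings, the calls of Wfdc18 and Clu were kept in 18, that of Anxa1 in 16, those of Ifitm1 and Myl7 in 11 and those of F13a1, Pmepa1 and Angptl4 in 10. Among gene groups, those of macrophages, Wnt targets and mast cells were higher and those of fatty acid oxidation lower with camera. None of these groups passed when the correlation was estimated (adjusted p = 0.11 to 0.359 with an estimated correlation).

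Macrophage and dendritic cell genes rose in polyp-free against wildtype sections (median 0.45 over 20 genes, camera adjusted p = 1.37e-10; adjusted p = 0.164 with an estimated correlation), with 0 calls over all genes by limma, 14 members higher at an unadjusted p under 0.05 and 10 rises adjusted over the list alone. The complement genes C1qb (1.31) and C1qc (1.17) and the receptor gene Csf1r (0.94) passed over the list alone. Wnt target genes rose (median 0.46 over 26 genes, camera adjusted p = 5.93e-07; adjusted p = 0.355 with an estimated correlation), with 8 rises adjusted over the list alone, Wif1 (4.34) and Notum (2.05) among them. Mast cell genes rose (median 0.44 over 12 genes, camera adjusted p = 0.000202; adjusted p = 0.359 with an estimated correlation), with 2 rises adjusted over the list alone, Mcpt1 (3.71) and Mcpt2 (3.70). Matrix remodelling protease genes rose (median 0.42 over 16 genes, camera adjusted p = 1.82e-06; adjusted p = 0.31 with an estimated correlation), with 5 rises adjusted over the list alone, such as Plat (3.04) and Mmp14 (1.37). Plasma cell genes rose (median 0.28 over 11 genes, camera adjusted p = 0.000307; adjusted p = 0.289 with an estimated correlation), with 2 rises adjusted over the list alone, Jchain (1.41) and Igha (1.35), subject to shared probes. YAP and fetal-type epithelial genes rose (median 0.55 over 12 genes, camera adjusted p = 0.000385; adjusted p = 0.359 with an estimated correlation), with 2 rises over all genes, Clu and Anxa1, and 5 rises and 1 fall adjusted over the list alone.

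Adipocyte genes rose (median 1.06 over 7 genes, camera adjusted p = 0.00141; adjusted p = 0.31 with an estimated correlation). There were 3 rises adjusted over the list alone, among them Adipoq (2.42) and Fabp4 (2.33), and their mean level was highest in replicate 3 of both Min groups, 8.01 and 7.95. Endothelial genes rose (median 0.28 over 14 genes, camera adjusted p = 0.0112; adjusted p = 0.355 with an estimated correlation), with 0 calls by limma, both over all genes and adjusted over the list alone, and 4 members higher at an unadjusted p under 0.05. Neutrophil genes rose (median 0.35 over 15 genes, camera adjusted p = 0.000202; adjusted p = 0.355 with an estimated correlation), with 2 rises adjusted over the list alone. Fatty acid oxidation genes fell (median -0.57 over 13 genes, camera adjusted p = 5.22e-08; adjusted p = 0.11 with an estimated correlation). There were 5 falls adjusted over the list alone, such as Pdk4 (-1.17) and Ehhadh (-1.03). Enteroendocrine cell genes fell (median -0.36 over 22 genes, camera adjusted p = 0.000515; adjusted p = 0.164 with an estimated correlation), with 1 fall adjusted over the list alone, Neurod1 (-0.72). Matrix and fibroblast genes rose (median 0.39 over 19 genes, camera adjusted p = 0.00411; adjusted p = 0.439 with an estimated correlation), with 4 members higher and 1 lower at an unadjusted p under 0.05. Absorptive enterocyte genes were lower with camera (median -0.42 over 20 genes, camera adjusted p = 0.0013; adjusted p = 0.607 with an estimated correlation), with 1 member lower at that threshold. Their mean difference of -0.49 became 0.07 without wildtype replicate 2, whose proximal intestine genes were also high (9.12 against 7.74 in replicate 1). The proximal and enterocyte lists share Lct (5.48 and 13.27 in wildtype replicates 1 and 2) and Fabp1 (10.39 and 12.2). Neither the matrix and fibroblast list nor the absorptive enterocyte list had calls by limma, over all genes or adjusted over the list alone. Lgr5 (0.20), Myc (0.21), Ptgs2 (0.80), Axin2 (-0.22), Il10 (0.11), Il17a (0.18), Foxp3 (0.03), Reg3g (0.21) and Lyz1 (-0.12) did not pass. Of these, Il10 and Foxp3 lay near background and Lyz1 near the highest values of the arrays.

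In all, 8 of 12393 genes changed between polyp-free and wildtype sections (limma, Benjamini-Hochberg adjusted p under 0.05), 7 higher and 1 lower, and 14 gene lists rose and 6 fell with camera, none of which passed with an estimated correlation. For 6 lists the mean difference moved by over 1.5 times without 1 array, as for endothelial genes without wildtype replicate 2 (0.28 to 0.18) and matrix and fibroblast genes without wildtype replicate 1 (0.28 to 0.16). All 8 genes also changed, the same way, between polyp-bearing and wildtype sections. Both comparisons use the same 2 wildtype arrays, too few to be split into sets of at least 2, so part of the overlap may come from them. In limma fits of 100 simulated sets of unchanged groups, 0 calls were shared, a value that leaves out any effect, and independent lists of these lengths would share 0.451 higher and 0.0416 lower genes. The log2 differences of the 2 comparisons correlated at 0.864 over genes with a covariance of 0.161, against means of 0.666 and 0.0448 in the simulated sets. The count was 0 without either wildtype array or without polyp-free replicate 2, 59 without polyp-free replicate 1, 4, 2, 14 and 2 without polyp-bearing replicates 1, 2, 3 and 4, and 0 with a limma fit of these groups alone, where 989 genes had an unadjusted p under 0.05. Array weights gave 687 genes, with weights of 5.66 for polyp-free replicate 2 and 0.143 to 0.912 for the other polyp-free arrays. The proximal intestine gene level as a covariate gave 44 and leaving out both arrays with the highest hybridisation controls 22. The mean of all probe sets gave 3 and every probe set by itself 5. With the replicate number as a block the count was 41. Since wildtype and Min arrays cannot be the same animal, that block is no check of pairing here.

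Polyp-bearing and polyp-free Min sections were compared to see what differs with the polyp within the mutant. Wnt target genes and growth genes were higher in the polyp-bearing sections as groups, and macrophage, MHC class II, T cell and smooth muscle genes were lower. These groups passed with camera, but none did when the correlation was estimated (adjusted p = 0.338 to 0.449 with an estimated correlation). No single gene passed over all genes tested. The lowest limma adjusted p, 0.0637, was that of Rnf43 (Entrez gene 207742), with 9.26 ± 0.17 (SD, n = 4) in polyp-bearing and 8.27 ± 0.26 (SD, n = 4) in polyp-free sections, a log2 difference of 0.99 ± 0.15 (SE). Lgr5 (Entrez gene 14160) was at 9.34 ± 0.15 (SD, n = 4) against 8.21 ± 0.46 (SD, n = 4), a difference of 1.13 ± 0.24 (SE; limma adjusted p = 0.0767), and every polyp-bearing array lay above every polyp-free array for both genes.

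Wnt target genes rose in polyp-bearing against polyp-free sections (median 0.75 over 26 genes, camera adjusted p = 1.14e-12; adjusted p = 0.338 with an estimated correlation). There were 20 rises and 1 fall adjusted over the list alone, although no gene passed over all genes. Wif1 (1.92), Tnfrsf19 (1.72), Notum (1.68) and Dkk2 (1.63) were among the rises. Intestinal stem cell genes rose (median 0.43 over 12 genes, camera adjusted p = 6.78e-05; adjusted p = 0.449 with an estimated correlation), with 6 rises adjusted over the list alone, including Lgr5, Rnf43, Sox9 (0.75) and Prom1 (0.64). Of these, Lgr5, Rnf43 and Sox9 are also on the Wnt list. Cell cycle genes rose (median 0.39 over 26 genes, camera adjusted p = 3.16e-07; adjusted p = 0.449 with an estimated correlation), with 2 rises adjusted over the list alone, Rrm2 (0.71) among them. Ribosome biogenesis genes rose (median 0.37 over 19 genes, camera adjusted p = 2.03e-07; adjusted p = 0.449 with an estimated correlation), with 5 rises adjusted over the list alone, Wdr43 (0.49) among them. Matrix remodelling protease genes rose (median 0.29 over 16 genes, camera adjusted p = 0.00017; adjusted p = 0.449 with an estimated correlation). There were 6 rises adjusted over the list alone, such as Plat (1.76), Timp1 (1.25) and Mmp14 (1.14). YAP and fetal-type epithelial genes rose (median 0.54 over 12 genes, camera adjusted p = 0.000738; adjusted p = 0.449 with an estimated correlation), with 4 rises adjusted over the list alone, Clu (1.37) and Anxa3 (1.11) among them. Mast cell genes rose between the Min groups too (median 0.49 over 12 genes, camera adjusted p = 0.00442; adjusted p = 0.469 with an estimated correlation), with 0 calls by limma, both over all genes and adjusted over the list alone, and 2 members higher at an unadjusted p under 0.05.

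Macrophage and dendritic cell genes fell in polyp-bearing against polyp-free sections (median -0.33 over 20 genes, camera adjusted p = 3.16e-07; adjusted p = 0.338 with an estimated correlation). There were 7 falls adjusted over the list alone, C1qc (-0.71) and Csf1r (-0.67) among them. MHC class II genes fell (median -0.50 over 6 genes, camera adjusted p = 1.1e-05; adjusted p = 0.363 with an estimated correlation), with 5 falls adjusted over the list alone, such as Cd74 (-0.78) and H2-DMa (-0.63). T cell genes fell (median -0.42 over 14 genes, camera adjusted p = 8.82e-05; adjusted p = 0.449 with an estimated correlation), with 0 calls by limma, both over all genes and adjusted over the list alone, and 5 members lower at an unadjusted p under 0.05. Interferon-stimulated genes fell (median -0.35 over 18 genes, camera adjusted p = 0.000122; adjusted p = 0.449 with an estimated correlation), with 2 falls adjusted over the list alone, Oasl2 (-0.86) and Psmb8 (-0.67). Enteroendocrine cell genes fell (median -0.33 over 22 genes, camera adjusted p = 0.000122; adjusted p = 0.315 with an estimated correlation), with 2 falls adjusted over the list alone, Sst (-0.78) among them. Smooth muscle genes fell (median -0.67 over 12 genes, camera adjusted p = 0.000198; adjusted p = 0.449 with an estimated correlation). There was 1 fall adjusted over the list alone, and their mean level was 7.69 in polyp-free replicate 1 against 9.05 to 9.20 in the other polyp-free arrays. Ptgs2 (1.18), Myc (0.45), Axin2 (0.45), Il10 (-0.20), Il17a (-0.15), Foxp3 (-0.18), Reg3g (-0.14) and Lyz1 (-0.04) did not pass. Again, Il10 and Foxp3 lay near background and Lyz1 near the highest values of the arrays.

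In all, 0 of 12393 genes passed a limma Benjamini-Hochberg adjusted p under 0.05 between polyp-bearing and polyp-free sections, and 1809 had an unadjusted p under 0.05, 1242 of them higher and 567 lower, where 619.65 are expected by chance. The groups did not overlap for 1148 genes, or 9.26%, where chance gives 2.86%. With camera, 9 gene lists rose and 12 fell, and none passed with an estimated correlation. The mean difference of 7 lists moved by over 1.5 times without 1 array: without polyp-free replicate 1 it went from 0.40 to 0.23 for cell cycle, from 0.37 to 0.23 for ribosome biogenesis and from -0.63 to -0.99 for smooth muscle genes, and without polyp-free replicate 2 from -0.42 to -0.26 for interferon-stimulated genes. Of the 35 ways to split the 8 Min arrays, 2 gave at least as many lists, so chance was not excluded for the number of lists. The gene count was 155 without polyp-bearing replicate 3, 39 without polyp-free replicate 4, 1 without polyp-free replicate 1, 38 without the lowest 40% of genes, 1237 with array weights and 1781 with the 3′ to 5′ ratio as a covariate. It was 97 with the replicate number as a block, although the labels do not tell whether equal numbers mark the same animal. The array weights were 5.66 for polyp-free replicate 2 and 0.143 to 0.912 for the other polyp-free arrays. The count with array weights thus rests largely on replicate 2 for the polyp-free group.

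**Figure D2:**
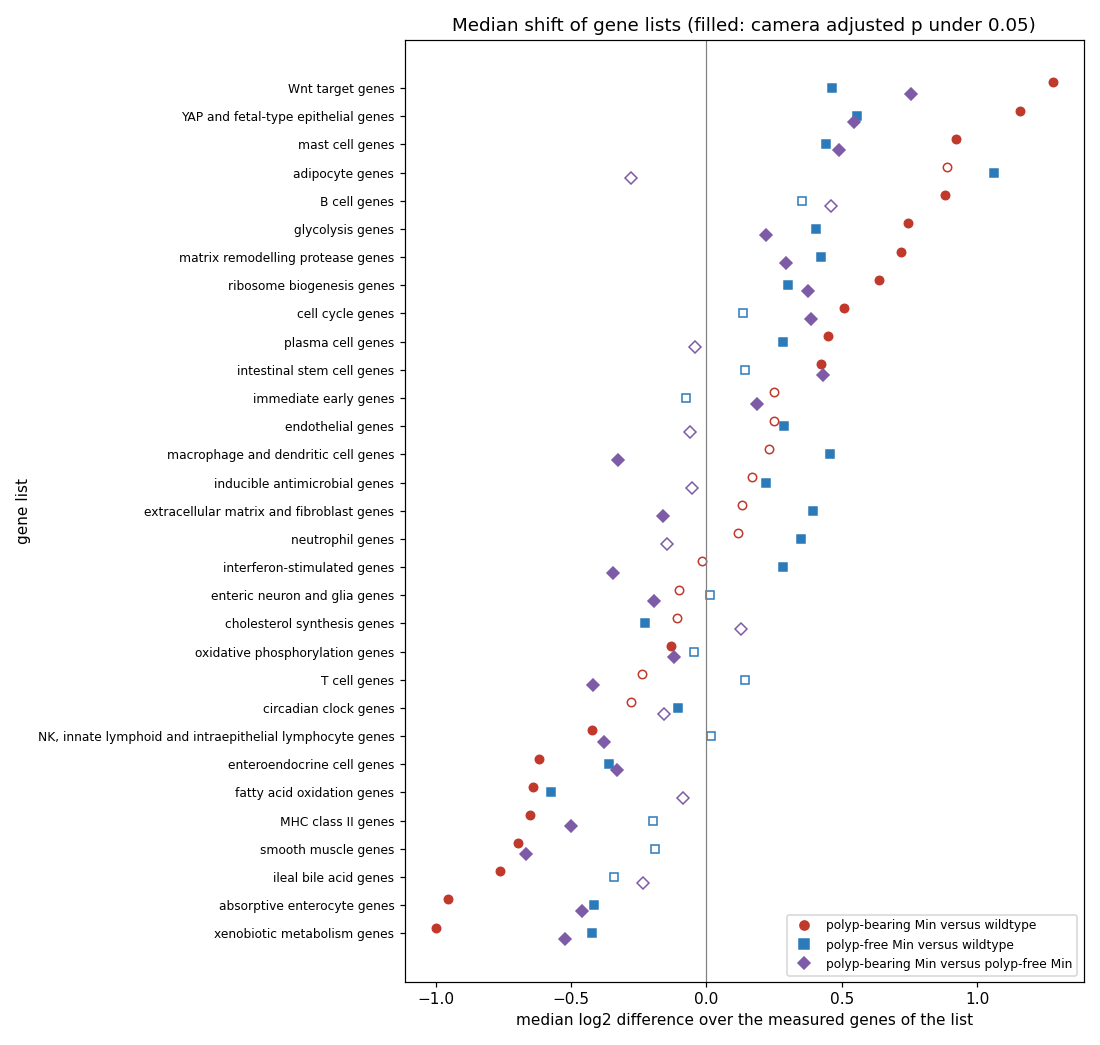
Median log2 difference (horizontal axis) of each gene list (vertical axis) in the 3 comparisons, for lists with a camera adjusted p under 0.05 in at least 1 of them; filled marks passed and open marks did not. Wnt target genes had medians of 1.28, 0.46 and 0.75, all filled, and macrophage and dendritic cell genes had filled medians of 0.45 and -0.33 on opposite sides of 0. The latter medians both use the same polyp-free arrays.

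**Figure D3:**
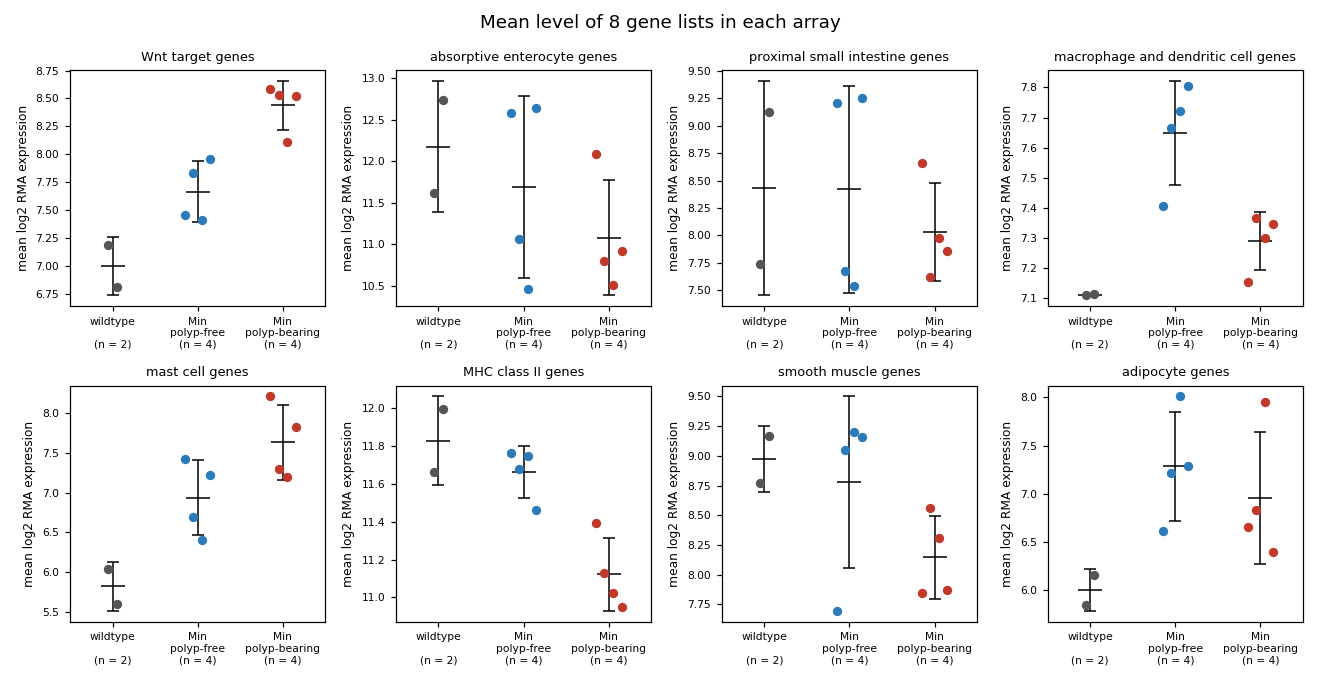
Mean log2 RMA expression (vertical axis) of 8 gene lists in each of the 10 arrays, by group (horizontal axis); points are arrays, and bars give the mean and SD. Smooth muscle genes lay at 7.69 in polyp-free replicate 1, below the other polyp-free arrays at 9.05 to 9.20.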

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

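Of the tests below, those of mixed adenoma tissue, the 3′ to 5′ ratio, the position of the section and the share of epithelium, and the count of splits for called genes, were chosen only after the result was seen. In groups of 4 arrays, 21 of 284 sets of values held an array far from the others by Dixon's test, where chance gives about 5%. In polyp-free replicate 1 these were the lists of smooth muscle (7.69), Paneth cell (10.32) and oxidative phosphorylation genes (12.42) and the genes C1qc (7.52), Myh11 (6.02), Tagln (7.92), Reg3g (12.97) and Rrs1 (8.52), all below the other 3 arrays. In polyp-bearing replicate 3 they were the lists of Wnt target (8.11), colon (6.54) and inflammatory cytokine and chemokine genes (5.69) and the genes Fn1 (8.57), Mmp13 (7.47), Plat (9.79) and Rnf43 (9.01), again below the others. In polyp-bearing replicate 1, xenobiotic metabolism genes (9.68) and Acaa1b (7.04) were above and Il10 (3.62) and Mcm4 (10.65) below the others. Polyp-bearing replicate 4 had a mean correlation with the other arrays of 0.979 and an interquartile range of 3.64, both the lowest of its group. Outside the named genes, 123 of 2246 probe sets with no single gene symbol passed between polyp-bearing and wildtype sections in the limma fit of every probe set, 75 higher and 48 lower.

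The 515 genes lower in polyp-bearing than in wildtype sections were also lower in polyp-free sections, by a mean log2 difference of -0.532 (95% interval -0.796 to -0.268), but they were picked against the same wildtype arrays, which favours a fall. With as many genes picked against 1 wildtype array and measured against the other, the difference was -0.623 (-1.26 to 0.0145) and -0.312 (-1.27 to 0.652), picked against replicate 1 first. The spread of these intervals comes from the Min arrays alone and is assumed for the lone wildtype array. On the linear scale, polyp-free arrays held a median over genes of 0.706 ± 0.188 (SD, n = 4) and 0.544 ± 0.339 of the fall. As shares of summed levels, the arrays lay between 0.405 and 0.933 and between -0.240 and 0.965. Shared noise of the wildtype arrays therefore cannot be told apart. Nor can the 3′ to 5′ ratio, with which the 2 differences were -0.488 (-1.12 to 0.146) and -0.262 (-1.41 to 0.889), or the position of the section, with -0.496 (-1.13 to 0.141) and -0.611 (-1.06 to -0.157) beside the proximal intestine gene level. Unseen adenoma tissue cannot be told apart either, since the share of the falls exceeded that of the rises by 0.347 ± 0.254 (SD, n = 4) and 0.278 ± 0.382, in the same order. The share of the rises itself was 0.359 ± 0.0801 (SD, n = 4) and 0.266 ± 0.124. What part of the rises comes from such tissue was not tested. A difference of genotype stays open and untested, with 2 wildtype arrays.

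Macrophage and dendritic cell genes were higher in polyp-free sections than in wildtype by 0.538 (95% interval 0.273 to 0.802) and than in polyp-bearing sections by 0.358 (0.142 to 0.574), as means over the list. With the adipocyte gene level as a covariate, the difference from wildtype was 0.419 (0.0495 to 0.789), with a lower bound close to 0. That level was 5.85 and 6.16 in wildtype and 6.62 to 8.01 in polyp-free arrays, without overlap. The covariate therefore cannot tell how much of this difference attached fat explains. Against polyp-bearing arrays, whose adipocyte level overlapped at 6.40 to 7.95, the difference was 0.328 (0.0997 to 0.557) with the covariate. A lower share of epithelium cannot be told apart: the macrophage list exceeded the endothelial list by 0.260 (0.0194 to 0.500) and the enteric neuron list by 0.541 (0.214 to 0.867) against wildtype, but the matrix and fibroblast list by 0.262 (-0.0453 to 0.570) and the smooth muscle list by 0.734 (-0.147 to 1.61). In the same comparison matrix and fibroblast genes rose (median 0.39, camera adjusted p = 0.00411; adjusted p = 0.439 with an estimated correlation) and absorptive enterocyte genes were lower (median -0.42, camera adjusted p = 0.0013; adjusted p = 0.607 with an estimated correlation), but the mean of the latter, -0.487, became 0.0709 without wildtype replicate 2, whose proximal intestine genes were high. Lct and Fabp1 are on both the enterocyte and the proximal list. A difference between mutant and wildtype mucosa stays open as a hypothesis.

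The 8 Min arrays can be split into 4 and 4 in 35 ways. All 35 gave at least the 0 genes of the real split by limma adjusted p, with 2 genes at most in the others, so that count excludes nothing. The 1809 genes at an unadjusted p under 0.05 were the most of any split, with 1715 the highest of the others. Only 1 of 35 was as large, the smallest share that 35 splits allow. The splits are equally likely under chance only if the 8 arrays come from separate animals, which the labels do not tell. Same-numbered Min arrays 2 and 3 correlated at 0.527 and 0.556 in their deviations, so chance cannot be excluded for that count. For gene lists, 2 of 35 splits gave as many as the real 21, with 23 the highest of the others, so chance cannot be excluded.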

How the results depend on the processing

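The tests with both covariates and without polyp-free replicate 1 and polyp-bearing replicate 4 together were chosen only after the result was seen. Between polyp-bearing and polyp-free sections, the 0 called genes became 97 with the replicate number as a block, 38 without the lowest 40% of genes, which leaves fewer tests, 1237 with array weights and 1781 with the 3′ to 5′ ratio as a covariate, and 0 to 155 when each array was left out. Between polyp-free and wildtype sections, the 8 genes became 41 with the block, 687 with array weights, 3 with the mean of all probe sets, 5 with every probe set by itself, 0 with only the compared groups, 22 without both arrays with high hybridisation controls and 44 with the proximal intestine gene level as a covariate, and 0 to 59 when each array was left out. Between polyp-bearing and wildtype sections, the 1314 genes became 485 with a fold of at least 2, 522 with the block, 2859 with array weights and 2155 with the 3′ to 5′ ratio, and 126 to 2205 when each array was left out. Of the 1314, 496 were also called with the block, 1313 with array weights and 854 with the ratio. Against wildtype the block is no check of pairing, since wildtype and Min arrays cannot be the same animal. Polyp-free replicate 2 had an array weight of 5.66, against 0.143 to 0.912 for the other polyp-free arrays. Same-numbered Min arrays correlated at 0.211, 0.527, 0.556 and -0.370 in their deviations, and polyp-bearing arrays 1 and 4 resembled polyp-free arrays 4 and 1 most. Apart from the fewer tests or arrays, the cause was not tested.

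Of 21, 20 and 19 lists called between polyp-bearing and polyp-free, polyp-free and wildtype, and polyp-bearing and wildtype sections, camera with an estimated correlation called 0, 0 and 0, with 5, 6 and 5 at an unadjusted p under 0.05, and fry called 4, 2 and 12. In the other settings 351 of 377, 332 of 357 and 322 of 342 list calls were kept, and none of the called lists changed direction in camera. These settings are not independent. Between the Min groups, the fits of the compared groups only and without either wildtype array are the same fit. Some settings also left out an array outside the comparison. The kept shares of lists and named genes therefore overstate how far the calls were challenged. The mean difference of absorptive enterocyte genes between polyp-free and wildtype sections changed sign, from -0.487 to 0.0709, without wildtype replicate 2. Of the values for named genes, 881 of 960, 760 of 894 and 1313 of 1464 kept their direction and their side of the threshold, and no gene that had passed changed direction. Those that changed direction had not passed. For polyp-bearing against polyp-free sections, Lyz1 was at 0.00155 with cyclic loess and between -0.10 and 0.00484 without single arrays, Il17a at 0.0149 with array weights, and Reg3g at 0.22 with the 3′ to 5′ ratio and between -0.57 and 0.0288 without single arrays. For polyp-free against wildtype, Reg3g was at -0.0771 with the block and -0.0469 to 0.64 without single arrays, Foxp3 at -0.0589 with cyclic loess, -0.0590 with array weights, -0.00755 without both arrays and -0.0222 to 0.0869 without single arrays, Apc at 0.0264 with the ratio, Lgr5 at -0.24 to 0.64 and Myc at -0.10 to 0.53 without single arrays. For polyp-bearing against wildtype, Reg3g was at -0.22 with the block, -0.00689 with median centring, -0.0207 without both arrays, -0.12 with the proximal level and -0.19 to 0.33 without single arrays, Apc at -0.0637 with median centring, -0.0254 with the mean of probe sets, -0.00250 with the proximal level and -0.0604 to 0.0647 without single arrays, Il17a at -0.0556 with median centring, -0.17 with the ratio and -0.0922 to 0.14 without single arrays, and Axin2 at -0.0437 with the mean of probe sets.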

Other observations

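Oxidative phosphorylation genes fell in polyp-bearing sections against wildtype (median -0.13 over 19 genes, camera adjusted p = 0.0283; adjusted p = 0.646 with an estimated correlation), with 2 falls by limma over all genes and 2 adjusted over the list alone. Circadian clock genes fell in polyp-free against wildtype sections (median -0.10 over 15 genes, camera adjusted p = 0.0208; adjusted p = 0.408 with an estimated correlation), with 2 falls adjusted over the list alone, and the repressor gene Cry2 differed by -0.80. Inducible antimicrobial genes rose in polyp-free against wildtype sections (median 0.22 over 17 genes, camera adjusted p = 0.0208; adjusted p = 0.427 with an estimated correlation), with 1 rise adjusted over the list alone, that of Retnlb (3.37). Goblet cell genes did not pass between polyp-bearing and wildtype sections, where their median (-0.22) and mean (0.20) differed in sign while Retnlb, 1 of their members, rose by 5.09. Neutrophil genes did not pass in that comparison either (camera adjusted p = 0.0712), although Ltf (2.91) and S100a9 (1.16) rose.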
